A study of Mus musculus with 6 samples.

How the data were processed

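RNA-seq was analysed from 6 libraries of cancer-associated fibroblasts sorted from mouse mammary tumours, 3 from WT mice and 3 from mPGES-1 KO mice as the labels give them. Per the labels' protocols, cDNA was made from the sorted cells with an ultra-low input template-switching kit and amplified by 16 PCR cycles, sheared, made into indexed libraries and sequenced as single reads of 75 cycles. These steps do not mark the strand of a read, and the reads carry no molecular identifiers, so counting intervals and floors cover counting error only. The surface markers of the sort are not given in the sources used here.

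The deposited values are raw read counts per gene symbol, whole numbers that the authors left without normalization, in 1 table of 18197 symbols and 6 columns, each matched to a sample by its label. The submitters' processing notes name FastQC 0.11.5, STAR and the mouse build mm10. The counting program, the annotation and any filter behind the deposited counts are not given in the sources used here. Each symbol had at least 11 counts in at least 1 library, no symbol was duplicated and no pair of libraries held identical values. Total counts ran from 23013498 to 43648450 per library, so 3 counts, the floor used for a gene at 0, stood for 0.0687 to 0.1304 CPM. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 also names, in which 17688 symbols were found and 509 were not, and 24 matched more than 1 gene.

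Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the genotype, scaled by TMM and fitted with a robust quasi-likelihood model (estimateDisp, glmQLFit, glmQLFTest) over all 6 libraries with no covariate. The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over 16543 genes, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is its absolute value over the square root of F. CPM values are counts over TMM-scaled library totals. The common biological coefficient of variation was 0.818, so only wide differences could be called: the smallest called log2 fold change was 1.13 in size and the median 2.45. The labels do not state that the libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical.

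In simulated counts drawn over 16543 genes from the gene means and spread of these libraries, the edgeR test recovered 1, 7, 38 and 42 of 50 genes changed by log2 folds of 1, 2, 4 and 6, with 7 false calls. On the same counts DESeq2 recovered 5, 23, 45 and 48 with 101 false calls, and limma-voom 1, 7, 29 and 35 with 4 false calls. Camera called the 1 simulated shifted list and 0 of the others among 39 random lists. The changed genes and the list members were drawn only from genes with an expected mean above 50 counts. Recovery of lower genes was therefore not measured. The simulated genes were drawn independently of each other, so this does not test false calls in lists whose members vary together. In the real lists the estimated correlation was, for example, 0.472 for pericyte markers and 0.826 for mitochondrially encoded transcripts.

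Before the data were examined, 39 gene lists were fixed, covering PGE2 and cAMP biology, fibroblast and matrix programmes, inflammatory and metabolic pathways, stress and RNA quality, and markers of other cell types a tumour sort could hold. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance and does not compare the list with other genes. The rule for named genes was also fixed then: Ptges; the 15 largest positive and negative log2 fold changes among called genes with a mean of at least 5 CPM and the groups apart, leaving out predicted genes, Rik names and pseudogenes; up to 4 members of each list, called members first; and Pdgfra, Pdgfrb, Col1a1, Fap, Acta2, S100a4, Epcam, Krt8, Ptprc and Pecam1. Csn3, Spp1, Igfbp7 and Malat1 are named as the most abundant gene of a library, and Rgs5, Cdh1, Elf3, Serpinh1 and Lif, all members of the fixed lists, were named after their values were seen. A few genes that the rule or a list picks out are not reported here. Of the 185 picked genes with a position, 26 share exonic bases with another tested gene.

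Other choices set at the same time were DESeq2 size factors and library size as scalings, no filter, a filter of 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, and a test against a log2 fold change of 1. Added after the data were seen were libraries thinned to the smallest total, loess offsets for GC content and transcript length (known for 97.7% of tested genes), and a fit without the luminal and pericyte markers. Principal components used log2 CPM with a prior count of 2. Figures were drawn with matplotlib 3.10.9.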

Results

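The series profiled cancer-associated fibroblasts, the stromal cells of the tumour that make and remodel its matrix, from mouse mammary tumours driven by the polyoma middle T oncogene. The cells were isolated by fluorescence-activated sorting from tumours harvested at 16 to 20 weeks in C57BL/6 mice. RNA-seq was run on 6 libraries, 3 labelled WT and 3 labelled mPGES-1 KO. The series title names a gene expression signature that depends on prostaglandin E2 (PGE2), the lipid mediator that microsomal prostaglandin E synthase-1 (mPGES-1) makes, so the question addressed is which transcripts differ between the genotypes. The count table held 18197 gene symbols. Total counts were 43648450, 37432510 and 37772405 in WT replicates 1, 2 and 3, and 27848682, 23013498 and 37249186 in mPGES-1 KO replicates 1, 2 and 3. Of the symbols, 16543 had enough counts to be tested.

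Ptges, the gene that encodes mPGES-1, was higher in the libraries labelled mPGES-1 KO, where loss of the whole transcript would make it lower. It reached 31.9, 19.2 and 27.9 CPM (counts scaled to library size) in the libraries labelled WT, replicates 1 to 3, and 186, 137 and 129 CPM in those labelled mPGES-1 KO. The means were 26.3 ± 6.49 and 150.3 ± 31.1 CPM (SD, n = 3 each), a log2 fold change of 2.51 ± 0.31 (SE) with an adjusted p = 0.0171 in edgeR's quasi-likelihood test. In the GENCODE M21 annotation of GRCm38, Ptges lies on the minus strand of chromosome 2 from 30889471 to 30929863, in 6 exonic blocks of 3931 bases together, none of them shared with another annotated gene. The deposited counts are totals per gene and do not separate a deleted part from the rest. The Ptges level therefore checks neither the deletion nor which labelled group carries it. Every direction given here is drawn from those labels, and the groups are called the libraries labelled WT and labelled mPGES-1 KO. The Ptges call was lost without WT replicate 2 (adjusted p = 0.0752), without mPGES-1 KO replicate 2 (0.0881) and without mPGES-1 KO replicate 3 (0.0658). It was also lost with the replicate number as a block (0.0803). Its log2 fold change stayed between 2.34 and 2.72 over 15 alternative settings, whose adjusted p ran from 2.32e-10 to 0.0881.

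**Figure D1:**
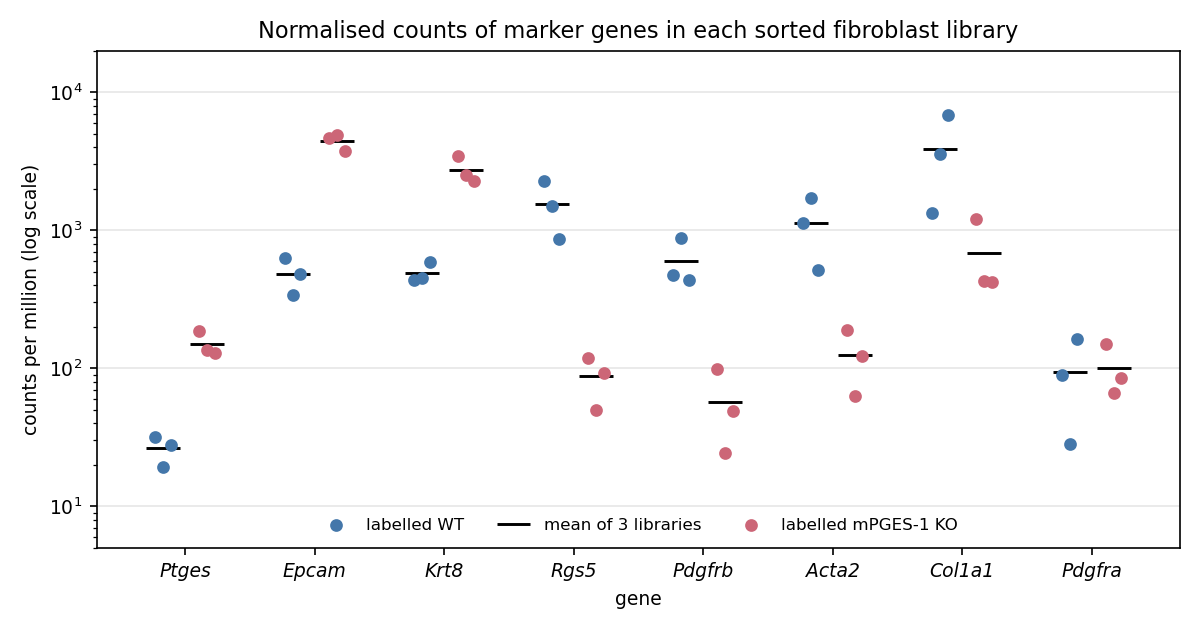
CPM, on a log scale, of 8 genes in each of the 3 libraries labelled WT and the 3 labelled mPGES-1 KO; points are libraries and bars are group means. Ptges, Epcam and Krt8 lie higher and Rgs5, Pdgfrb, Acta2 and Col1a1 lower in all 3 libraries labelled mPGES-1 KO, while Pdgfra overlaps between the groups.

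The libraries labelled mPGES-1 KO carried less RNA of most pericyte markers and of some contractile and matrix genes, and more RNA of some luminal epithelial genes, of the chemokines Cxcl1 and Cxcl2 and of several NF-kB targets. Rgs5, a regulator of G protein signalling used as a pericyte marker, fell from 1554 ± 717 to 87.4 ± 35.2 CPM, and Acta2, the smooth muscle actin of myofibroblasts, fell from 1120 ± 598 to 125 ± 62.4 CPM. Epcam, an epithelial adhesion molecule, rose from 484 ± 147 to 4443 ± 615 CPM, and the chemokine gene Cxcl2 rose from 61.7 to 845 CPM (mean ± SD, n = 3 per group, or the mean alone). In all, 456 of the 16543 genes tested passed an adjusted p of 0.05, 198 of them higher and 258 lower in the libraries labelled mPGES-1 KO, and 443 of them protein coding. In each of the 456 genes all 3 libraries of a group lay on one side of the other group. This separation was seen in 4614 of all tested genes, or 27.9%, where chance gives 10%.

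The pericyte list had the largest median difference of all lists. Of 14 tested pericyte and vascular smooth muscle markers, 11 fell, 0 rose and 3 did not pass, and 14 were lower when adjusted over the list alone. Higd1b fell from 638 ± 425 to 7.73 ± 4.38 CPM, Ndufa4l2 from 729.6 ± 273.5 to 13.8 ± 7.89 CPM, Esam from 245 ± 130 to 4.81 ± 2.38 CPM and Pdgfrb from 598 ± 251 to 57.4 ± 38.0 CPM. The list median was -4.43 on the log2 scale (camera, adjusted p = 6.63e-32, and adjusted p = 0.167 with an estimated correlation). Together these markers took 0.644 ± 0.283% of the counts in the libraries labelled WT and 0.0321 ± 0.0104% in those labelled mPGES-1 KO. Of 22 tested luminal mammary epithelium markers, 6 rose, 0 fell and 16 did not pass, and 14 were higher when adjusted over the list alone. Krt8 rose from 493 ± 83.9 to 2754 ± 642 CPM and Krt18, its keratin partner, from 1038 ± 240.5 to 4958 ± 132 CPM, and Trf, Cdh1 and Elf3 rose by log2 fold changes of 2.41 ± 0.25, 2.26 ± 0.33 and 2.45 ± 0.39 (SE). The luminal median was 1.68 (adjusted p = 3.57e-15, and adjusted p = 0.0547 with an estimated correlation), and these markers took 1.78 ± 0.320% of counts against 5.03 ± 0.582%. Csn3, the milk protein kappa-casein, held the most counts of any gene in each library labelled mPGES-1 KO, at 3.16%, 1.73% and 1.78%, while Spp1, Igfbp7 and Malat1 led the libraries labelled WT. The Csn3 difference itself did not pass (log2 fold change 1.99 ± 0.46, adjusted p = 0.0667).

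General fibroblast genes did not pass as a group, though the values of the list shifted with single libraries. Pdgfra, the receptor commonly used to mark fibroblasts, was at 93.4 ± 67.4 CPM in the libraries labelled WT and 101 ± 44.7 CPM in those labelled mPGES-1 KO (adjusted p = 0.952), and its small log2 fold change of 0.11 turned negative without WT replicate 2, without mPGES-1 KO replicate 1 and with offsets for GC content and length. Fap had a log2 fold change of -0.67 ± 0.56 (adjusted p = 0.589) and S100a4 of -1.73 ± 1.00 (adjusted p = 0.413). Over 15 alternatives Fap ran from -1.47, without mPGES-1 KO replicate 1, to -0.21, without mPGES-1 KO replicate 2, and S100a4 from -2.69 to -1.23. Among 21 universal and steady-state fibroblast genes, Dpp4 alone rose, with an adjusted p of 0.05 to 2 significant digits (0.04997), 20 did not pass and the median was 0.19 (camera adjusted p = 0.521). Over its alternatives that median ran from -0.25 to 0.96 and the adjusted p from 0.00476 to 0.906, and the list was called in 1 of 16, without WT replicate 3. The leukocyte marker Ptprc had a log2 fold change of 2.27 ± 0.65 (adjusted p = 0.109) and the endothelial marker Pecam1 of 2.39 ± 1.36 (adjusted p = 0.407). Over 15 alternatives Ptprc ran from 1.48 to 2.63 and passed in DESeq2 alone (adjusted p = 0.00551, in a range up to 0.299). Pecam1 ran from 1.85 to 5.35, the highest without WT replicate 2, which held 6.77 CPM against 0.296 and 0.357 CPM in WT replicates 1 and 3.

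Some contractile and matrix genes fell in the libraries that also held fewer pericyte markers. Of 16 myofibroblast contractile genes, 8 fell and 0 rose, and 11 were lower when adjusted over the list alone. Tgfb1i1, a focal adhesion protein, fell from 211 ± 23.4 to 26.9 ± 4.12 CPM, Myl9, a myosin light chain, from 859 ± 382 to 72.9 ± 30.3 CPM, and Mylk, the kinase of that light chain, from 202 ± 142 to 11.4 ± 3.93 CPM. The median of the list was -2.50 (adjusted p = 1.54e-12, and adjusted p = 0.344 with an estimated correlation). Of 20 fibrillar collagen and cross-linking genes, 6 fell and 0 rose, and 13 were lower when adjusted over the list alone. These included Col8a1 (209 to 20.3 CPM), Col5a3 (416 to 58.3 CPM), Col12a1 (109 to 20.2 CPM) and Serpinh1, the collagen chaperone (1325 to 238 CPM). The collagen list had a median of -1.88 (adjusted p = 3.44e-10, and adjusted p = 0.499 with an estimated correlation). Col1a1, the main fibrillar collagen chain, did not pass, with 3897 ± 2765 CPM in the libraries labelled WT and 689 ± 453 CPM in those labelled mPGES-1 KO (log2 fold change -2.50 ± 0.68, adjusted p = 0.1003).

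Among matrix proteases and inhibitors, 5 of 21 fell and 0 rose (9 lower when adjusted over the list alone), with Mmp11 going from 575 ± 423 to 25.1 ± 10.8 CPM, Timp1 from 443 ± 218.5 to 88.4 ± 34.2 CPM and Mmp14, a membrane-bound collagenase, from 649.5 ± 118.9 to 184 ± 79.4 CPM. Its median was -1.49 (adjusted p = 1.05e-06, and adjusted p = 0.499 with an estimated correlation). Among 15 basement membrane genes, 4 fell and 0 rose (7 lower and 1 higher when adjusted over the list alone), with Col4a1 going from 1474 ± 627 to 166 ± 92.8 CPM and Col18a1 from 346 ± 112 to 31.1 ± 16.1 CPM, and the median was -1.42 (adjusted p = 1.76e-05, and adjusted p = 0.499 with an estimated correlation). Of 24 matrix glycoproteins and proteoglycans, Sparc alone was called, falling from 9561 ± 2577 to 2113 ± 939 CPM, while 3 were lower when adjusted over the list alone. The median of that list was -0.70 (adjusted p = 0.0232, and adjusted p = 0.705 with an estimated correlation). It ran from -1.28 to -0.01 over 16 alternatives, 11 of which called it (adjusted p from 2.56e-04 to 0.705), and was nearest 0 without WT replicate 3. In the same libraries labelled mPGES-1 KO, the share of counts on pericyte markers was 20-fold lower than in those labelled WT.

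Some cytokine and NF-kB genes rose in the libraries that also held more luminal markers. Of 17 NF-kB targets, 4 rose and 0 fell, and 6 were higher when adjusted over the list alone; all 17 had a positive log2 fold change. Tnfaip3, a feedback inhibitor of the pathway, rose from 67.5 ± 9.36 to 302 ± 65.9 CPM, Ier3 from 683 ± 170 to 4286 ± 1192 CPM, Nfkbiz from 214 ± 25.7 to 672 ± 40.0 CPM and Nfkb1 from 42.9 ± 18.4 to 209 ± 99.2 CPM. The NF-kB list had a median of 1.42 (adjusted p = 1.15e-07, and adjusted p = 0.167 with an estimated correlation). Of 22 inflammatory fibroblast cytokines and chemokines, 3 rose and 0 fell, and 6 were higher and 1 lower when adjusted over the list alone. Besides Cxcl2 these were Cxcl1 (762 ± 212 to 3598 ± 858 CPM) and Lcn2, an iron-binding acute phase protein (1983 ± 901 to 10230 ± 2471 CPM), while Lif (20.0 to 400 CPM, adjusted p = 0.0568) and Saa3 (119 to 5.86 CPM, adjusted p = 0.0517) did not pass. The list median was 0.54 (adjusted p = 0.0112, and adjusted p = 0.575 with an estimated correlation) and became -0.12 (adjusted p = 0.116) without mPGES-1 KO replicate 1, within a range of 1.96e-04 to 0.575 over its alternatives. The luminal share of counts was 2.83-fold higher in these same libraries labelled mPGES-1 KO.

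In the PGE2 group itself, 2 of 14 genes rose, 0 fell, and 3 were higher when adjusted over the list alone. Next to Ptges, Pla2g4a, the phospholipase that frees arachidonic acid, rose from 22.2 ± 8.12 to 132 ± 33.8 CPM. Ptgs2, which encodes cyclooxygenase-2, was at 12.8 ± 7.63 and 58.1 ± 22.2 CPM (adjusted p = 0.0925), and Ptges2, another PGE2 synthase, at 73.4 ± 6.01 and 37.9 ± 11.02 CPM (adjusted p = 0.140). The list median was 0.37 (adjusted p = 0.0427, and adjusted p = 0.499 with an estimated correlation). This list includes Ptges, the targeted gene, and was not tested without it. Its median ran from 0.14 to 0.67 over 16 alternatives, 9 of which called the list (adjusted p from 0.00564 to 0.499). Of 20 cAMP and CREB early response genes, Pde4b, a cAMP phosphodiesterase, rose from 117 ± 32.5 to 603 ± 107 CPM and the stress transcription factor Atf3 from 531 ± 201 to 4027 ± 306 CPM, and 0 fell. Adjusted over the list alone, 3 were higher and 1 was lower. This list passed with 10 positive and 10 negative log2 fold changes and a median of 0.05 (adjusted p = 0.0476, and adjusted p = 0.705 with an estimated correlation). Its median turned negative and its call was lost without WT replicate 1 (-0.11, adjusted p = 0.297) and without mPGES-1 KO replicate 3 (-0.07, adjusted p = 0.114), within a range of 5.85e-04 to 0.705 over its alternatives. The libraries labelled mPGES-1 KO in which these genes were measured also held the higher shares of luminal marker counts (5.03% against 1.78%) and of mitochondrially encoded counts (3.44% against 1.77%).

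**Figure D2:**
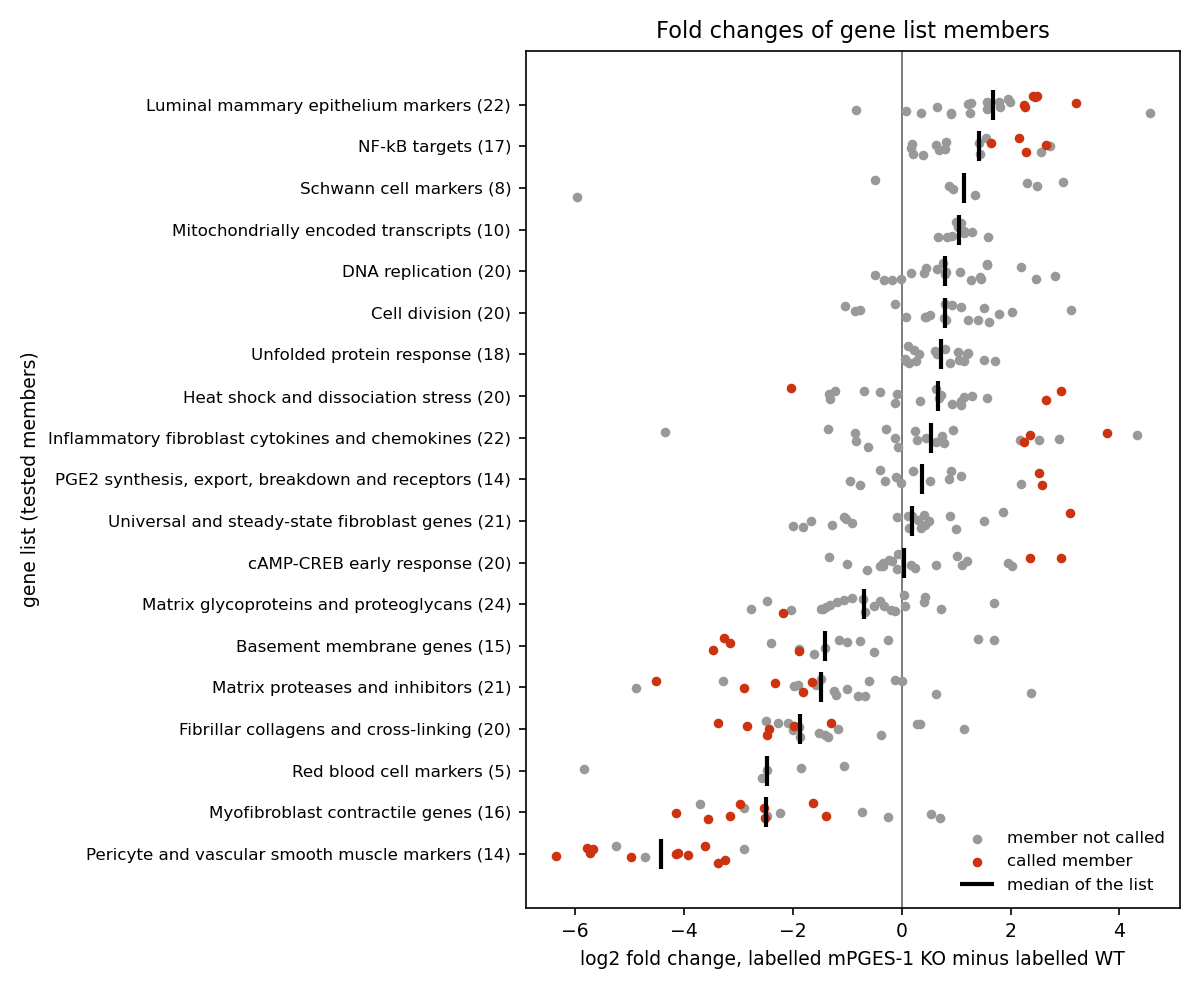
Log2 fold changes (labelled mPGES-1 KO minus labelled WT, horizontal axis) of the tested members of the 18 gene lists that passed camera and of the universal fibroblast list; each point is a gene, red where called, and each vertical bar is the median of the list. The pericyte list has its median at -4.43 and the luminal list at 1.68, and the universal fibroblast list has its median at 0.19.

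The 15 largest increases and decreases among genes past the threshold, at a mean of at least 5 CPM and with the groups apart, held further signalling genes. Csf3, which encodes the granulocyte growth factor G-CSF, rose from 4.49 ± 5.15 to 1148 ± 495 CPM (log2 fold change 8.00 ± 1.45), and Il23a, a subunit of interleukin-23, from 0.303 ± 0.327 to 121 ± 137 CPM. The Il23a level was uneven, at 275.9, 71.2 and 16.1 CPM in mPGES-1 KO replicates 1 to 3, and its log2 fold change ran from 7.16 to 10.08 over 15 alternatives. Hbegf, a ligand of the EGF receptor, rose from 37.8 ± 20.0 to 535 ± 83.2 CPM, Ovol1, an epithelial transcriptional repressor, from 9.72 ± 4.86 to 154 ± 31.6 CPM, and Fosl1, an AP-1 subunit, from 5.84 ± 4.85 to 126 ± 33.2 CPM. The others were Hepacam2, Lypd3, Scin, Rnd1, Clca3a2, Trp53inp1, Sgms2 and Cxcl2, with log2 fold changes from 3.77 to 4.39, and Plet1os at 4.46. Fignl1 had 2 counts in all in the libraries labelled WT and 863 in those labelled mPGES-1 KO, a ratio of 582 with a 95% counting interval of 161 to 4810. Exons of Fosl1 and Plet1os overlap the opposite-strand genes Ccdc85b (57.2% of exonic bases) and Plet1 (21%), and the reads hold no strand, so these values are uncertain. The same holds for Lypd3 (13.6% shared), Ovol1 (19.8%) and Pdgfa (26.1%), which also overlap opposite-strand genes. Trf (63.5%) and S100a4 (51.7%) share exonic bases with annotated genes on the same strand, so their values are uncertain as well.

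Among the decreases, Rasl12, a small GTPase-like gene, had the smallest adjusted p of all genes (0.00730) and fell from 162 ± 74.5 to 0.563 ± 0.139 CPM. Jph2 and Mrvi1, which act in muscle calcium handling and smooth muscle relaxation, had log2 fold changes of -8.05 ± 1.52 and -7.67 ± 1.28. Gper1, a membrane oestrogen receptor, had no count in any library labelled mPGES-1 KO against 33.7 ± 23.5 CPM, which makes it at least 318-fold lower when each of those libraries is set at 3 counts. By the same bound H2-M9 was at least 281-fold, Stac at least 144-fold and Fhl5 at least 116-fold lower. H2-M9 belongs to a family of closely related class I genes among which reads may be divided, so its value is uncertain, as is that of Clca3a2 among its paralogs. Insc had 1 count in all in the libraries labelled mPGES-1 KO and 1802 in those labelled WT, a ratio of 1340 with an interval of 239 to 52800. Map3k7cl, Adap2, Higd1b, Ndst3, Jaml and Zfp280b were also among them, with log2 fold changes from -8.35 to -6.06. These counting intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

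Of the 39 gene lists, 18 passed camera, 11 higher and 7 lower in the libraries labelled mPGES-1 KO. Those not yet named had few or no called members, and were measured in the same libraries whose share of luminal marker counts was 5.03% against 1.78%. All 18 unfolded protein response genes had a positive log2 fold change, with 0 called, 2 higher when adjusted over the list alone and a median of 0.72 (adjusted p = 0.00134, and adjusted p = 0.499 with an estimated correlation). The 10 mitochondrially encoded transcripts had a median of 1.06 with 0 called by either adjustment (adjusted p = 9.29e-04, and adjusted p = 0.575 with an estimated correlation), and took 1.77 ± 1.03% of counts in the libraries labelled WT and 3.44 ± 0.706% in those labelled mPGES-1 KO. The 20 DNA replication genes had a median of 0.80, 0 called and 5 higher when adjusted over the list alone (adjusted p = 0.00662, and adjusted p = 0.575 with an estimated correlation), and the 20 cell division genes a median of 0.80 with 0 called by either adjustment (adjusted p = 0.0481, and adjusted p = 0.768 with an estimated correlation). The cell division list was called in 7 of 16 alternatives (adjusted p from 5.31e-05 to 0.768). Of 20 heat shock and dissociation stress genes, Ier3 and Atf3 rose and Socs3, a feedback inhibitor of cytokine signalling, fell from 819 ± 118 to 200.3 ± 60.01 CPM. Adjusted over the list alone, 8 of these were higher and 3 lower, with a median of 0.66 (adjusted p = 0.0232, and adjusted p = 0.568 with an estimated correlation). The 8 Schwann cell markers had a median of 1.14 and 0 called, 4 being higher and 1 lower when adjusted over the list alone (adjusted p = 0.0481, and adjusted p = 0.499 with an estimated correlation). That median ran from 0.14, without mPGES-1 KO replicate 1, to 1.499 over 16 alternatives, 6 of which called the list (adjusted p from 0.0171 to 0.499). The 5 red blood cell markers had a median of -2.47 and 0 called, 3 being lower when adjusted over the list alone (adjusted p = 0.00473, and adjusted p = 0.568 with an estimated correlation).

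The other 21 lists did not pass. Single members did, among them these: Map2k3 rose in the p38 and JNK list (median 0.13, adjusted p = 0.673), Skil rose in the TGF-beta list (-0.09, 0.817), and Ero1l and Vegfa rose in the glycolysis and hypoxia list (0.24, 0.1004). Vegfa rose and Pdgfa fell in the angiogenic list (0.24, 0.521), Nbl1 fell in the Wnt and BMP list (-0.26, 0.0865), Sfn rose among basal epithelium markers (0.74, 0.196), Cd14 rose among macrophage markers (0.39, 0.0957) and Esam, shared with the pericyte list, fell among endothelial markers (-0.61, 0.0745). No member was called among other prostanoid synthases and receptors (median -1.15, adjusted p = 0.196), antigen-presenting fibroblast genes (0.15, 0.521), complement genes (-0.57, 0.348), type I interferon genes (0.02, 0.577), interferon gamma and MHC class I genes (-0.01, 0.829), nuclear oxidative phosphorylation genes (-0.33, 0.217), cholesterol and fatty acid synthesis genes (-0.04, 0.494) or cytosolic ribosomal proteins (-0.23, 0.324). The same held for markers of neutrophils (-1.10, 0.829), T and NK cells (1.62, 0.195), B and plasma cells (0.90, 0.872) and adipocytes (0.33, 0.966). In these 21 lists the calls adjusted over the list alone matched in number those over all genes, except for TGF-beta (1 higher, 2 lower), glycolysis and hypoxia (3 higher, 1 lower), angiogenic factors (1 higher, 2 lower), Wnt and BMP (0 higher, 2 lower) and endothelial markers (0 higher, 4 lower). Several of these results depend on the setting. Of 16 alternatives, 5 called the endothelial list (median from -1.82 to 0.26, adjusted p from 0.00564 to 0.705) and 4 the macrophage list (-0.63 to 1.85, 0.00173 to 0.950). The glycolysis and hypoxia list was called in 4 (0.03 to 0.49, 0.0148 to 0.716), the T and NK cell list in 3 (-0.19 to 2.63, 0.0225 to 0.768) and the Wnt and BMP list in 2 (-1.17 to 0.19, 0.0390 to 0.651). The basal (0.34 to 1.396, 0.0284 to 0.568) and ribosomal (-0.36 to -0.07, 0.0433 to 0.906) lists were called in 1 each. The medians of the B cell (-0.71 to 1.55), adipocyte (-0.69 to 0.74), neutrophil (-1.59 to 0.01), antigen-presenting (-1.10 to 1.54) and angiogenic (-0.15 to 0.86) lists took both signs without a call, as did those of the p38 and JNK, TGF-beta, cholesterol and both interferon lists. Median, mean and test differed in sign for the p38 and JNK, TGF-beta, type I interferon, interferon gamma, cholesterol, B cell and adipocyte lists.

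The libraries of the labelled genotypes lay apart on the main axis of variation, and libraries of the same label lay apart on the next. The first principal component of log2 CPM held 35.5% of the variance and placed the libraries labelled WT between -140.4 and -76.6 and those labelled mPGES-1 KO between 66.4 and 141.3. The second held 24.98% and placed WT replicate 1 at 146.2, apart from WT replicates 2 and 3 at -62.4 and -108.5. Correlations across genes ran from 0.798 to 0.898 within the libraries labelled WT, from 0.803 to 0.854 within those labelled mPGES-1 KO and from 0.745 to 0.811 between the groups. The number of called genes rested on single libraries: it was 568 without WT replicate 1, 1 (Rasl12) without WT replicate 2, 150 without WT replicate 3, 160 without mPGES-1 KO replicate 1, and 0 in edgeR without mPGES-1 KO replicate 2 or replicate 3, where 2574 and 2975 genes had an unadjusted p under 0.05, against 3157 with all libraries. No call of a fixed list held with an estimated correlation in camera, where 4 of the fixed lists had an unadjusted p under 0.05. In contrast, fry called 3 of them (luminal, pericyte and NF-kB).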

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

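The tests added after the data were seen are thinning, GC and length offsets, and the fit without luminal and pericyte markers. No named gene or list was called in the opposite direction in any setting, and all 456 calls were called in the same direction by DESeq2, 435 of them by limma-voom. For the genes this was nearly fixed beforehand, so it says little about robustness. The settings share the same counts, and in all 456 genes the groups lay apart. A setting that called 0 genes could not show a reversed gene call. The counts of called genes (all, higher, lower) were 2093, 996 and 1097 with the DESeq2 Wald test and 1944, 977 and 967 with limma-voom, and in simulated counts DESeq2 also gave more false calls. They were 1113, 480 and 633 at an adjusted p under 0.1, 57, 19 and 38 against a log2 fold change of 1, and 299, 135 and 164 with GC and length offsets, where the cause was not tested. Leaving out 1 library gave between 0 and 568 called genes, 0 and 327 higher and 0 and 241 lower, and 57.6% higher without WT replicate 1 against 43.4% with all libraries. With fewer libraries the test has less power, but why each library weighs so differently was not tested. In those fits Ptges had log2 fold changes of 2.34 to 2.71. Other scalings, filters, thinning (513) and the fit without the markers (429) left the count between 429 and 585. Camera passed 18 lists, 15 to 20 under the other scalings, filters, offsets, tools and left-out libraries (15 to 19 for left-out libraries alone), 0 with an estimated correlation and 3 with fry.

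The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.063, 0.028 and -0.017, and not every library correlated best with its own number. With the replicate block edgeR called 0 genes, 0 higher and 0 lower, while 2716 had an unadjusted p under 0.05. Ptges then had a log2 fold change of 2.53 (adjusted p = 0.0803, range over its alternatives 2.32e-10 to 0.0881). Depth limited low genes mainly: a gene under 0.0687 to 0.1304 CPM could not be told from 0.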

Other observations

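The lists in the next paragraph were chosen after the main test had been seen, when members such as Kit, Sox9, Klf5, Ovol1 and Nr2f2 were already known to be called, so their p-values are not independent evidence. The p-values of these later lists were adjusted among themselves only, over fewer lists than those fixed beforehand. Their adjusted p-values therefore cannot be ranked against those of the fixed lists, such as the luminal list. The tests on pericyte loss, epithelial RNA, a label swap, exchanged genotype names and stress, with the left-out libraries in them, were also chosen after the results they bear on were seen. The tests on depth, the chromosome segment, the progenitor profile, the mesenchymal factors and the other splits were set before their values were computed.

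The called transcription factors of epithelial cells were higher, and most of the called mesenchymal ones lower, in the libraries labelled mPGES-1 KO. All 18 tested epithelial factors had a positive log2 fold change and 6 rose, among them Ovol1, Ehf, Elf3, Klf5 and Sox9, with a median of 1.79 (camera adjusted p = 1.08e-13, and adjusted p = 0.0174 with an estimated correlation). Sox9 went from 145 ± 47.8 to 963 ± 50.3 CPM and Klf5 from 20.7 ± 3.84 to 120.3 ± 28.1 CPM (SD, n = 3). Among 21 epithelial junction genes, 4 rose, among them Ocln, Marveld2 and Crb3, and 0 fell, with a median of 1.71 (adjusted p = 1.24e-11, and adjusted p = 0.0170 with an estimated correlation). Of 22 mesenchymal factors, 7 fell (Zeb2, Prrx1, Tbx2, Meox2, Ebf1, Foxs1 and Nr2f2) and 1 rose (Hey1), with a median of -1.96 (adjusted p = 1.32e-10, and adjusted p = 0.0800 with an estimated correlation). Whether the mesenchymal factors fell with the pericyte and contractile genes stays open, since members of the list were known to be called and its median of -1.959 only restates the fall. A hypothesis that the epithelial RNA has the profile of luminal progenitors rather than of hormone-sensing cells cannot be told apart from its opposite. Kit, Cd14, Tspan8, Sox9 and Ehf rose among 15 progenitor markers and Prlr among 14 hormone-sensing markers. The progenitor median was 1.10 and the hormone-sensing median 1.62, a difference of -0.515 with a 95% bootstrap interval over members of -1.09 to 1.20. The order of the medians is thus the reverse of the hypothesis. It meets the condition set beforehand for its failure, a hormone-sensing median at or above the progenitor median. The wide interval, which takes both signs, still keeps the question open.

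The first pattern is the fall of pericyte markers with the rise of luminal markers. Lower depth of the libraries labelled mPGES-1 KO is argued against, since 100% of the 17 called pericyte and luminal members stayed called after thinning all libraries to 23013498 counts. Loss of pericytes alone from an unchanged mixture would raise all other cells alike. The luminal median exceeded the universal fibroblast median by 1.491 (95% bootstrap interval over members 0.855 to 2.704), but by 0.51 (-0.174 to 1.514) without WT replicate 3. These intervals treat members as independent, though the estimated correlation of the universal list was 0.729. Medians of other cell types reached from -2.47 for red blood cells to 1.62 for T and NK cells, with 0 members called in either list. These values do not settle the question and keep this explanation open. More epithelial RNA in those libraries stays open as well, since the 95.5% of luminal members with a positive log2 fold change restate the pattern and test nothing about its source. Whether that RNA comes from cells that passed the sort, from free RNA or from fibroblasts that express epithelial genes, and whether genotype changed the makeup of the tumour stroma, was not tested.

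The second pattern is Ptges, higher in the libraries labelled mPGES-1 KO. A single swap or wrong label as the whole cause is argued against, since it would leave a library within the range of the other group, while the lowest labelled mPGES-1 KO held 4.03 times the CPM of the highest labelled WT. A common rise of the whole chromosome segment is argued against by the 165 tested genes within 5 Mb. Their median of -0.408 lay within the middle 95% of windows of as many genes on other chromosomes (-0.511 to 0.349), though near its lower end. A median cannot show changes of single neighbours, so a segment that alters only some of its genes stays open. Of these neighbours 3 were called, among them Lcn2, which starts at 32384633. Epithelial RNA that carries counted Ptges reads stays open. The Ptges log2 fold change lay 0.831 above the luminal median and within the wide range of luminal members (-0.84 to 4.56). That range also takes in unchanged genes and some lower ones, so lying within it says nothing about the source of the reads. A deletion that leaves part of the gene transcribed would still be counted. Exchanged genotype names cannot be told apart from these explanations: all 3 libraries labelled mPGES-1 KO lay above every library labelled WT, and gene totals do not show the deleted part.

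The third pattern is the higher level of NF-kB targets, with single stress genes among the called ones. Handling stress during dissociation cannot be told from a genotype effect, as 60% of the heat shock and dissociation genes had a positive log2 fold change, with Ier3 and Atf3 up and Socs3 down. Ier3 is also among the called NF-kB targets, so it is not separate evidence of stress. Uncalled early response genes of the list went both ways, with log2 fold changes of -0.09 for Fos, -0.39 for Egr1, -1.33 for Ier2 and 0.64 for Fosb. Epithelial RNA that carries the NF-kB and stress transcripts cannot be told apart either, because the groups share no level of luminal markers. The mean log2 CPM of luminal markers in the lowest library labelled mPGES-1 KO exceeded that of the highest labelled WT by 1.348. Among libraries of the same label, the relation of NF-kB targets to luminal content depended on the measure. Mean log2 CPM was 5.26, 5.99 and 5.63 for NF-kB targets and 6.95, 6.66 and 6.78 for luminal markers in WT replicates 1 to 3, and 7.30, 6.89 and 6.64 against 8.30, 8.53 and 8.54 in mPGES-1 KO replicates 1 to 3. These orders run opposite ways within each label. By share of counts, however, mPGES-1 KO replicate 1 was highest in both. The shares were 1.157%, 0.822% and 0.773% for NF-kB targets and 5.695%, 4.625% and 4.762% for luminal markers in mPGES-1 KO replicates 1 to 3. Csn3, a member of the luminal list, alone took 3.163%, 1.727% and 1.782% of counts in these libraries. The high luminal share of mPGES-1 KO replicate 1 thus rests largely on this gene. In WT replicates 1 to 3 the shares were 0.259%, 0.283% and 0.274% for NF-kB targets against 1.84%, 1.43% and 2.06% for luminal markers. With 3 libraries per label and close luminal values, neither the spread within a label nor the difference between labels is settled. An effect of the genotype remains untested.

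The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 456 genes, the highest of the other splits called 0, and 1 split, the real one, reached the real count.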
